A study of Mus musculus with 8 samples.

How the data were processed

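RNA-seq libraries of CJ9 mouse embryonic stem cells at day 4 after withdrawal of leukemia inhibitory factor were compared: 2 of wild-type (WT) cells, 3 of Evx1as knockout (KO) cells and 3 labelled EVX1 KO. Groups and replicate numbers were taken from the sample labels. Expression was deposited as 1 table of FPKM (fragments scaled to transcript length and to the number of mapped fragments) for all 8 libraries. Per the labels, libraries were made with a TruSeq Stranded kit. CASAVA, TopHat2 2.0.11 and the mouse builds mm10 and mm9 are named, with no role given, per the submitters' processing notes. The program that computed FPKM, the annotation and the strand setting of the counting are not given in the sources used here.

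The deposited table held 45772 lines, of which 3527 were blank and 42245 had FPKM values. These carried 38610 symbols, of which 11633 were XLOC identifiers with no gene name. Of these symbols 2660 stood on several lines, each with the same FPKM values, and were used once. Status LOWDATA was set on 334 lines of 197 symbols, of which 46 were among the genes tested. Of 22443 symbols matched to GENCODE genes on GRCm38, 2623 (11.7%) overlapped them in position, so the coordinates of the table are not those of GRCm38. Positions are given as in the deposited table. Of the builds named, mm10 is GRCm38, which leaves mm9, but positions were not checked against mm9. Genes that share reads with an overlapping gene, an antisense partner or a pseudogene copy are uncertain.

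The table gives no read counts, so absolute depth is unknown and no counting interval can be given. Relative depth was estimated from the smallest steps between low FPKM values of the same gene in different libraries, and 34.5% to 48.0% of the low-value genes used lay at the estimated step. The 10 highest genes held 9.66% to 11.2% of summed FPKM. Low FPKM values rest on few reads, and some values listed at 0 may be failed estimates, so single libraries are given for such genes.

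Genes with at least 1 FPKM in at least 2 of the 8 libraries were kept (13188 genes). Log2(FPKM + 1) values of all 8 libraries entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, empirical Bayes with an intensity trend, two-sided), so that the groups shared 1 estimate of the spread. Benjamini-Hochberg adjusted p under 0.05 was called a change. The FPKM scale was not rescaled. Comparisons were Evx1as KO against WT, EVX1 KO against WT and EVX1 KO against Evx1as KO. No batch is given in the labels. Files were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

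Groups, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. There were 24 lists: naive and general pluripotency, primed epiblast, primitive streak and mesendoderm, definitive endoderm, extraembryonic endoderm, mesoderm, cardiac muscle, blood and endothelium, neuroectoderm, Wnt targets, Nodal targets, BMP targets, the Hoxa cluster and other Evx1 neighbours, other Hox genes, epithelial to mesenchymal transition, trophoblast, fibroblasts or feeder cells, the 2-cell-like state, germ cell genes, imprinted genes, p53 targets, hypoxia and glycolysis, Y-linked genes, and proliferation. Members overlap between lists. The 20 lists with at least 4 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Fry, which asks whether a list's genes move on balance in the same direction, called 17, 2 and 14 lists in the comparisons in the order above.

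Evx1 and Evx1as were always named. For each knockout against WT, the 10 largest rises and 10 largest falls on the log2 scale were named among called genes whose knockout libraries all lay beyond both WT libraries. For EVX1 KO against Evx1as KO, 5 each way were named among called genes whose groups did not overlap. From each list, up to 4 tested members with the largest absolute log2 fold change in the comparison described were eligible, and the text gives a selection of them. A few genes that the rule or a list would name are not reported here. Lines with no symbol, ribosomal protein pseudogenes and predicted Gm genes were passed over, which affected 4 rises in Evx1as KO, 1 rise in EVX1 KO and 2 falls in the direct comparison. Most called members of a list were also named where there were 5 or fewer, and these were chosen after their values were seen.

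The comparisons against WT share their control libraries, so 100 sets of unchanged groups were simulated against shared controls. After seeing the data, 100 more were added in which each knockout kept the fold changes of its called genes, with those of EVX1 KO assigned to random genes. The steps were tested on simulated data in which known genes were changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 46.4%, 90.7% and 98.6% were recovered for Evx1as KO against WT (12850 genes). The shares were 50.7%, 88.6% and 100% for EVX1 KO against WT (12836 genes) and 66.7%, 92.6% and 100% for EVX1 KO against Evx1as KO (12839 genes). False calls made up 5.81%, 3.66% and 5.95% of calls. Camera called 5 of 5 shifted lists and 0 unshifted ones, at either correlation, in simulated Evx1as KO against WT (12835 genes). Simulated genes varied independently of each other, so this gives no check of the preset correlation for lists whose genes vary together. In the data the estimated correlation ran from −0.19 to 0.52 over the lists tested.

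Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median-ratio scaling, limma without trend or with robust moderation, array weights, a fit of only the groups compared, a replicate block, a minimum change of 2-fold, and leaving out each library in turn. Leaving out the genes of chromosomes 1, 8 and 14 was added after seeing the data. Chromosome medians were taken over genes with a mean of at least 5 FPKM. Sequence variants, splicing and the edited sequences were not analysed here.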

Results

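RNA-seq was performed on CJ9 mouse embryonic stem cells of the 129S4/SvJae strain after 4 days without leukemia inhibitory factor, the cytokine that holds these cells in the undifferentiated state. Evx1as is a long noncoding RNA of the Evx1 locus, and Evx1 encodes a homeobox transcription factor of the primitive streak. There were 2 libraries of wild-type (WT) cells, 3 of Evx1as knockout (KO) cells and 3 labelled EVX1 KO, with the knockouts made by CRISPR according to the series title. Expression was deposited as FPKM, which is scaled to transcript length and library size, and summed to between 531523 and 587798 per library. Between 12244 and 12442 genes reached 1 FPKM in each library. Absolute depth was unknown. Steps between low values put the depth of WT replicate 2 at 1.19 times that of WT replicate 1. By the same measure the Evx1as KO libraries stood at 0.863, 0.914 and 0.976 and the libraries labelled EVX1 KO at 1.01, 0.989 and 1.04. Nothing in the labels says that replicates came from separate cultures. P-values thus measure only the spread between these samples, which may be technical in part.

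Across 13188 genes, which are not independent replicates, log2(FPKM + 1) values of the WT libraries correlated at r = 0.986. The range was 0.983 to 0.987 among Evx1as KO libraries and 0.979 to 0.987 among those labelled EVX1 KO. It was 0.950 to 0.968 between WT and Evx1as KO, 0.970 to 0.983 between WT and EVX1 KO, and 0.952 to 0.969 between the knockouts. The first principal component held 50.9% of the variance and placed the WT libraries at −22.4 and −22.5. Libraries labelled EVX1 KO lay at −12.7, −20.7 and −20.4 on it, and Evx1as KO libraries at 37.5, 22.0 and 39.3. The second component, with 18.2% of the variance, placed the WT libraries at 21.4 and 19.6, those labelled EVX1 KO at −27.9, −16.9 and −2.69, and the Evx1as KO libraries at −0.785, 5.47 and 1.78.

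Genes of chromosomes 1, 8 and 14 shifted together in some libraries, as seen over 8282 genes with a mean of at least 5 FPKM. The chromosome 8 median, relative to each gene's mean over all libraries, lay at −0.38 and −0.31 (log2) in replicates 1 and 2 labelled EVX1 KO and at 0.07 in their replicate 3. In the WT and Evx1as KO libraries it lay between 0.01 and 0.16. The chromosome 14 median lay at −0.37 and −0.34 in Evx1as KO replicates 2 and 3, at 0.12 in their replicate 1, and between −0.03 and 0.18 in the other groups. Chromosome 1 lay at 0.14, 0.12 and 0.11 in the libraries labelled EVX1 KO, at −0.11, −0.09 and −0.08 in Evx1as KO, and at 0.03 and −0.10 in WT. Medians of the other 17 chromosomes lay between −0.06 and 0.05. For chromosome 8 in the libraries labelled EVX1 KO, 1000 random sets of as many genes had medians between −0.04 and 0.04. For chromosome 14 in Evx1as KO they lay between −0.05 and 0.06. The differences between replicates argue against all replicates of either knockout being repeats of 1 culture.

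**Figure D1:**
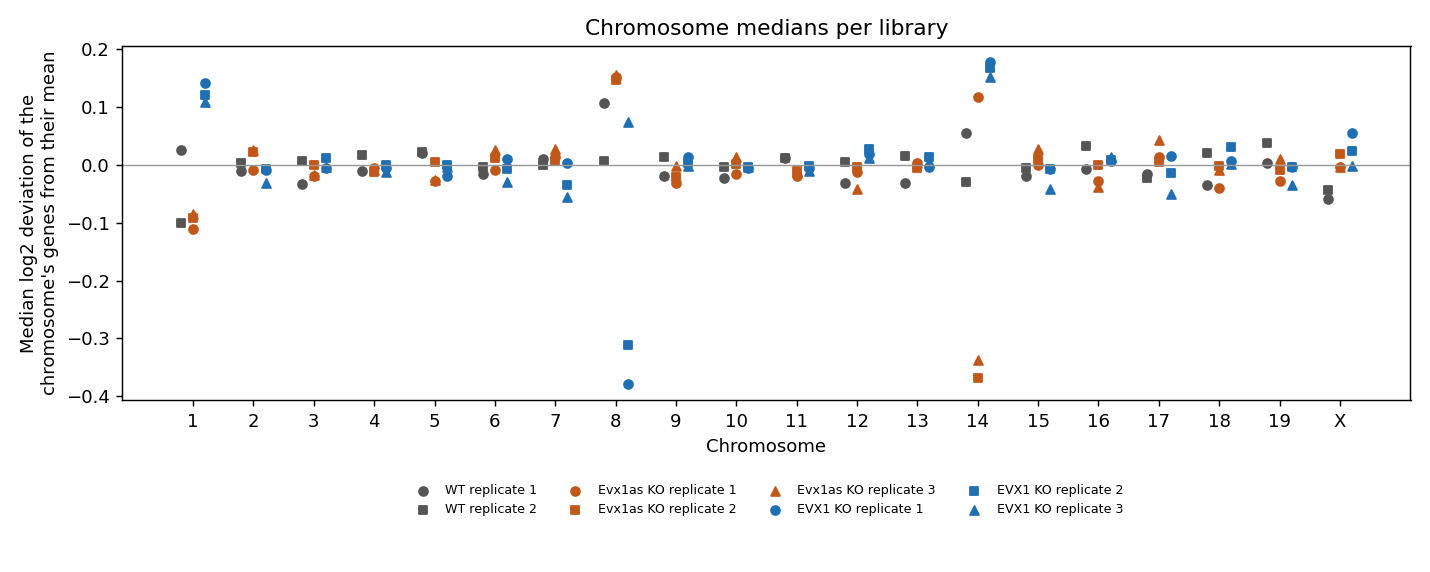
Median log2 deviation of each chromosome's genes from their mean over the 8 libraries (vertical axis) by chromosome (horizontal axis), with 1 point per library, coloured by group and shaped by replicate. Chromosome 8 lies at −0.38 and −0.31 in EVX1 KO replicates 1 and 2 and chromosome 14 at −0.37 and −0.34 in Evx1as KO replicates 2 and 3.

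The targeted genes were examined first. Evx1as, listed as 5730457N03Rik (chromosome 6, 52258382 to 52264826 in the coordinates of the deposited table), fell from 6.05 ± 0.986 FPKM in WT to 0.0690 ± 0.0302 in Evx1as KO (SD, n = 2 and 3). Its log2 fold change, here and throughout on the log2(FPKM + 1) scale that understates changes of low genes, was −2.72 ± 0.21 (standard error, adjusted p = 3.25e-04). Evx1 (chromosome 6, 52263491 to 52268372) fell from 26.6 ± 6.50 to 2.28 ± 1.66 FPKM in the same cells (log2 fold change −3.20 ± 0.41, adjusted p = 0.00180). In the libraries labelled EVX1 KO, Evx1 stood at 26.3, 20.8 and 31.7 FPKM against 22.0 and 31.2 in WT (log2 fold change −0.01 ± 0.41, adjusted p = 0.988). Evx1as stood at 7.07 ± 1.92 FPKM there (log2 fold change 0.17 ± 0.21, adjusted p = 0.667). Evx1 transcript thus did not set the libraries labelled EVX1 KO apart from WT and gives no check of that label, and EVX1 KO is used here only as the name of these libraries. The position of the edit is not given in the sources used here. Evx1 and Evx1as overlap by 1336 bp and the counting strand is not stated, so their reads in the overlap cannot be separated.

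**Figure D2:**
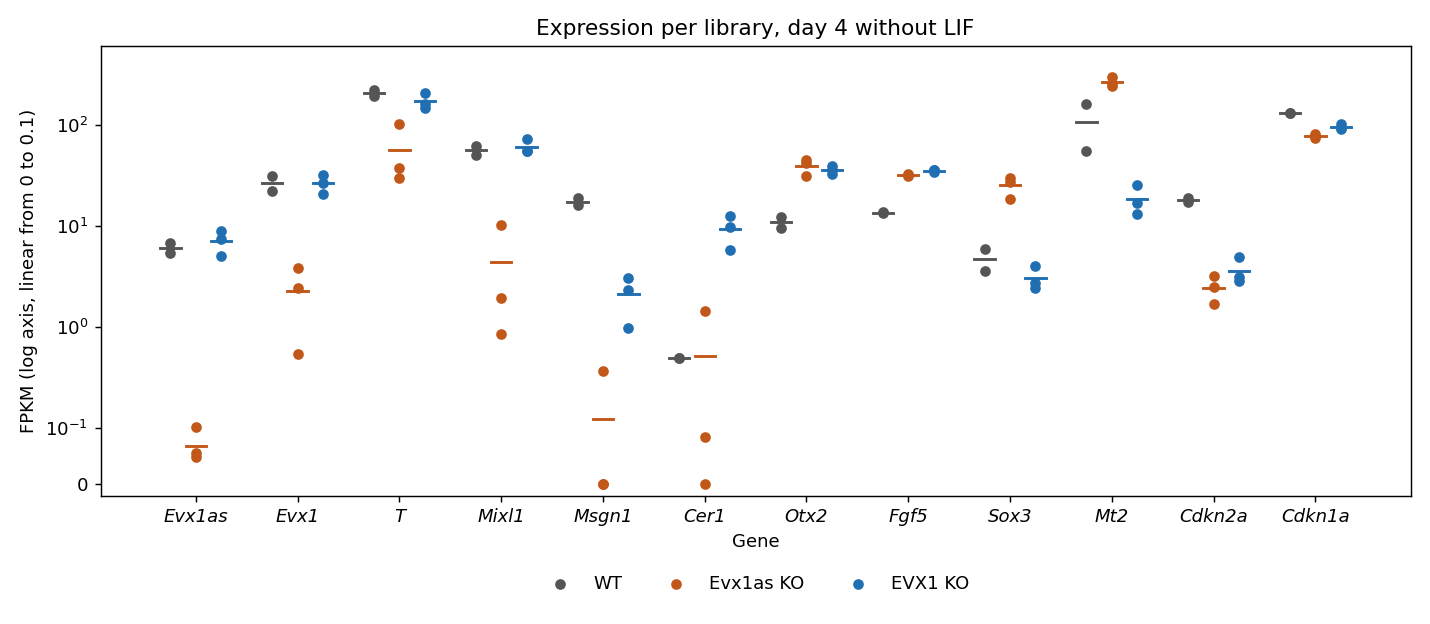
FPKM per library (vertical axis, logarithmic above 0.1 and linear from 0 to 0.1) of 12 genes, with points for libraries, coloured by group, and bars for group means. Evx1 stands at 26.3, 20.8 and 31.7 FPKM in the libraries labelled EVX1 KO against 22.0 and 31.2 in WT.

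The first comparison asked which genes differ between Evx1as KO and WT cells during differentiation. Most of the primitive streak and mesoderm genes tested were lower in Evx1as KO. T (Brachyury), a T-box factor of the streak and nascent mesoderm, fell from 206 ± 20.9 to 56.1 ± 39.5 FPKM (SD, n = 2 and 3; log2 fold change −2.07 ± 0.42, adjusted p = 0.00950). Mixl1, a homeobox factor of mesendoderm, fell from 55.8 ± 8.55 to 4.37 ± 5.16 FPKM (log2 fold change −3.84 ± 0.60, adjusted p = 0.00348). Mesp1, a marker of early cardiac mesoderm, stood at 21.6 and 19.3 FPKM in WT and was listed at 0, 0.949 and 0.297 in Evx1as KO (log2 fold change −3.97 ± 0.56, adjusted p = 0.00247). Of 18 tested streak and mesendoderm genes 15 fell and 0 rose (0 up and 15 down adjusted over the list alone). The streak and mesendoderm median log2 fold change was −1.82 (camera adjusted p = 4.20e-09, adjusted p = 0.147 with an estimated correlation). Foxa2 (−0.09 ± 0.51), Nodal (−0.28 ± 0.15) and Cer1 (−0.11 ± 0.40) did not pass. Mixl1 stood at 10.3 FPKM in Evx1as KO replicate 2, against 0.855 and 1.95 in replicates 1 and 3. T was not called without WT replicate 1 or 2 (adjusted p up to 0.0654). With 1 WT library left out, the other is assumed to vary like the other groups.

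Among 12 mesoderm genes 9 fell and 0 rose (0 up and 11 down adjusted over the list alone). Msgn1, a regulator of presomitic mesoderm, stood at 18.7 and 16.1 FPKM in WT and was listed at 0, 0.367 and 0 in Evx1as KO (log2 fold change −4.05 ± 0.29, adjusted p = 2.80e-04). Kdr, a receptor gene of blood and vessel progenitors, fell from 7.32 ± 4.24 to 0.263 ± 0.127 FPKM (log2 fold change −2.62 ± 0.38, adjusted p = 0.00275). The mesoderm median was −1.70 (camera adjusted p = 3.41e-07, adjusted p = 0.147 with an estimated correlation). Of 4 blood and endothelium genes Kdr, Gata2 and Runx1 fell (0 up and 3 down adjusted over the list alone), with a median of −0.85 (camera adjusted p = 0.00536, adjusted p = 0.169 with an estimated correlation). Of 5 cardiac muscle genes Actc1 and Tnnc1 fell (0 up and 2 down adjusted over the list alone), and the cardiac median was −0.85 (camera adjusted p = 0.0427, adjusted p = 0.228 with an estimated correlation). That list was not called without Evx1as KO replicate 1 (adjusted p = 0.0620), Evx1as KO replicate 2 (0.0908) or EVX1 KO replicate 2 (0.0565), nor with median-ratio scaling (adjusted p = 0.0525) or with array weights (0.0620). Tnnc1 was not called without WT replicate 1 or 2 or Evx1as KO replicate 1 or 2 (adjusted p up to 0.211), nor was Runx1 without WT replicate 1 or 2 or any Evx1as KO replicate (adjusted p up to 0.145). Actc1 was not called without WT replicate 2, any Evx1as KO replicate or EVX1 KO replicate 2 or 3 (adjusted p up to 0.321). The log2 fold change of Actc1 (−1.07) ranged from −1.63 without WT replicate 1 to −0.50 without WT replicate 2. Tnnc1 lies on chromosome 14, whose genes were lower in Evx1as KO replicates 2 and 3.

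Most tested targets of Wnt and BMP signalling, pathways that act in streak formation, were also lower. Cdx2, a caudal-type homeobox gene, fell from 11.9 ± 3.55 to 1.03 ± 0.544 FPKM (log2 fold change −2.67 ± 0.23, adjusted p = 5.50e-04). Of 14 Wnt targets 10 fell and Tcf7 rose (1 up and 12 down adjusted over the list alone). The Wnt target median was −1.05 (camera adjusted p = 2.04e-06, adjusted p = 0.147 with an estimated correlation). Msx1, a homeobox target of BMP signalling, fell from 47.9 ± 2.46 to 3.39 ± 3.82 FPKM (log2 fold change −3.82 ± 0.53, adjusted p = 0.00236). Of 11 BMP targets 9 fell and 0 rose (0 up and 11 down adjusted over the list alone). The BMP target median was −1.06 (camera adjusted p = 9.14e-07, adjusted p = 0.147 with an estimated correlation). Bmp4 itself, on chromosome 14, fell by 1.70 (log2). Of 10 Nodal targets Eomes, Gsc and Smad7 fell and Gdf3 rose (2 up and 4 down adjusted over the list alone), and the Nodal target median was −0.28 (camera adjusted p = 0.231, adjusted p = 0.547 with an estimated correlation). Eomes was not called without WT replicate 1 or 2 (adjusted p up to 0.0653), nor was Gdf3 without WT replicate 1 or any Evx1as KO replicate (adjusted p up to 0.215). Gsc was not called without WT replicate 1 or 2 or Evx1as KO replicate 1 or 3 (adjusted p up to 0.156). Smad7 was not called without WT replicate 1 or 2, Evx1as KO replicate 2 or 3 or EVX1 KO replicate 2 (adjusted p up to 0.213). Tcf7 was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 2 (adjusted p up to 0.225). The rise of Gdf3 (0.69) ranged from 0.33 without WT replicate 1 to 1.06 without WT replicate 2.

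Some genes of migrating and supporting tissues fell too. The cadherin gene Cdh2 fell from 22.8 ± 2.48 to 2.90 ± 2.11 FPKM (log2 fold change −2.73 ± 0.33, adjusted p = 0.00149), and Snai1, a repressor of epithelial genes, from 33.5 ± 7.64 to 5.23 ± 2.66 (log2 fold change −2.54 ± 0.36, adjusted p = 0.00264). Of 12 genes of epithelial to mesenchymal transition 6 fell and Epcam rose (1 up and 9 down adjusted over the list alone). The median of that list was −0.57 (camera adjusted p = 2.57e-04, adjusted p = 0.147 with an estimated correlation). Acta2, the smooth muscle actin gene, fell from 152 ± 52.8 to 25.5 ± 8.04 FPKM (log2 fold change −2.53 ± 0.36, adjusted p = 0.00263). Of 10 markers of fibroblasts or feeder cells 6 fell and Mmp2 rose (1 up and 7 down adjusted over the list alone), and the fibroblast median was −0.87 (camera adjusted p = 0.00658, adjusted p = 0.147 with an estimated correlation). The fibroblast call was lost with a filter of 5 FPKM (adjusted p = 0.143). Of 10 trophoblast markers, among them the streak genes Eomes, Cdx2 and Hand1, 7 fell and 0 rose (0 up and 10 down adjusted over the list alone). The trophoblast median was −1.31 (camera adjusted p = 9.14e-07, adjusted p = 0.147 with an estimated correlation). Hand1 was not called without WT replicate 1 (adjusted p = 0.0677), nor was Eomes without WT replicate 1 or 2 (adjusted p up to 0.0653). Epcam was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 (adjusted p up to 0.176).

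Some endoderm genes fell as well. Gata4, a zinc finger gene of endoderm and heart on chromosome 14, fell from 11.4 ± 6.57 to 0.524 ± 0.258 FPKM (log2 fold change −2.93 ± 0.35, adjusted p = 0.00149). Of 11 definitive endoderm genes Gata4, Gata6, Cxcr4 and Gsc fell and 0 rose (0 up and 4 down adjusted over the list alone). The definitive endoderm median was −0.31 (camera adjusted p = 0.0289, adjusted p = 0.394 with an estimated correlation). Its call was lost without Evx1as KO replicate 1 (adjusted p = 0.0545) or 3 (0.0516) and without the genes of chromosomes 1, 8 and 14 (median −0.10, adjusted p = 0.311). The call was also lost in a fit of only the 2 groups (adjusted p = 0.0552), where the median lay further from 0, at −0.97. Of 10 extraembryonic endoderm genes 6 fell and 0 rose (0 up and 6 down adjusted over the list alone), and the extraembryonic median was −0.66 (camera adjusted p = 2.98e-04, adjusted p = 0.147 with an estimated correlation). Gsc was not called without WT replicate 1 or 2 or Evx1as KO replicate 1 or 3 (adjusted p up to 0.156).

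Most tested genes of the primed epiblast, the state that follows naive pluripotency, were higher in Evx1as KO. Foxd3, a forkhead factor of the epiblast, rose from 0.699 ± 0.0684 to 6.14 ± 0.499 FPKM (log2 fold change 2.07 ± 0.15, adjusted p = 2.84e-04). The DNA methyltransferase gene Dnmt3b rose from 54.5 ± 8.92 to 191 ± 13.6 FPKM (log2 fold change 1.80 ± 0.16, adjusted p = 5.91e-04). Of 11 primed epiblast genes 8 rose and Lef1 fell (9 up and 1 down adjusted over the list alone). The primed epiblast median was 1.36 (camera adjusted p = 5.90e-06, adjusted p = 0.147 with an estimated correlation). Sox2, a core pluripotency and neural factor, rose from 15.2 ± 5.04 to 50.4 ± 10.1 FPKM (log2 fold change 1.68 ± 0.22, adjusted p = 0.00217), and Tbx3 fell from 27.1 ± 11.3 to 3.58 ± 1.65 (log2 fold change −2.62 ± 0.38, adjusted p = 0.00282). Of 17 naive and general pluripotency genes Sox2, Nanog, Utf1, Pou5f1 and Lin28a rose, and Tbx3, Klf2, Klf4, Klf5 and Dppa2 fell, with Klf2 on chromosome 8 and Klf5 on chromosome 14 (5 up and 5 down adjusted over the list alone). The pluripotency median was 0.12 (camera adjusted p = 0.835, adjusted p = 0.871 with an estimated correlation), while its mean (−0.08) and test pointed down. Klf4 was not called without WT replicate 1 (adjusted p = 0.0512), nor was Klf5 without WT replicate 2 (adjusted p = 0.0764). Lin28a was not called without WT replicate 1 or Evx1as KO replicate 3 (adjusted p up to 0.0976), nor was Pou5f1 without WT replicate 1 or 2 or Evx1as KO replicate 1 or 2 (adjusted p up to 0.136). Klf2 was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 or 3 (adjusted p up to 0.224). The rise of Utf1 (1.52) ranged from 1.00 without WT replicate 1 to 2.04 without WT replicate 2.

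Sox3, a neural SoxB1 gene, rose from 4.74 ± 1.65 to 25.1 ± 5.86 FPKM (log2 fold change 2.19 ± 0.25, adjusted p = 0.00122). Of 8 neuroectoderm genes 2 rose, Sox3 and Sox1, and 1 fell (2 up and 1 down adjusted over the list alone), and the neuroectoderm median was 0.05 (camera adjusted p = 0.430, adjusted p = 0.486 with an estimated correlation). Pdk1, a kinase gene that restrains pyruvate oxidation, rose from 5.26 ± 0.113 to 15.6 ± 2.48 FPKM (log2 fold change 1.39 ± 0.25, adjusted p = 0.00629). Of 17 hypoxia and glycolysis genes 6 rose and 0 fell (8 up and 0 down adjusted over the list alone), and the glycolysis median was 0.36 (camera adjusted p = 0.00207, adjusted p = 0.228 with an estimated correlation). Of 15 proliferation genes the mitotic genes Bub1, Ccnb1, Ccnb2 and Aurkb and the replication gene Mcm2 rose and 0 fell (5 up and 0 down adjusted over the list alone). The proliferation median was 0.23 (camera adjusted p = 8.69e-04, adjusted p = 0.199 with an estimated correlation). Bub1 and Ccnb1 were not called without WT replicate 1 (adjusted p up to 0.0900), nor were Ccnb2, Aurkb and Mcm2 without WT replicate 1 or 2 or Evx1as KO replicate 1 or 3 (adjusted p up to 0.146).

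Mdm2, the ubiquitin ligase gene that p53 induces, fell from 91.5 ± 3.62 to 50.3 ± 3.92 FPKM (log2 fold change −0.85 ± 0.09, adjusted p = 0.00102). Of 15 p53 targets 10 fell and the apoptosis gene Bbc3 rose (1 up and 10 down adjusted over the list alone). The p53 target median was −0.55 (camera adjusted p = 1.20e-04, adjusted p = 0.147 with an estimated correlation). Peg10, a paternally expressed gene, fell from 370 ± 38.1 to 150 ± 24.6 FPKM (log2 fold change −1.30 ± 0.13, adjusted p = 9.32e-04). Of 21 imprinted genes 8 fell and Grb10 and Meg3 rose (4 up and 9 down adjusted over the list alone), and the imprinted median was −0.24 (camera adjusted p = 0.0396, adjusted p = 0.228 with an estimated correlation). This list was not called without Evx1as KO replicate 1 (median −0.13, adjusted p = 0.0578) or 3 (median −0.25, adjusted p = 0.0716), nor without WT replicate 2 (median −0.34). The call was also lost with a filter of 5 FPKM (adjusted p = 0.116) or with quantile normalization (0.0605). Bbc3 was not called without WT replicate 1 or 2 or Evx1as KO replicate 1 or 3 (adjusted p up to 0.123). Meg3 was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 2 (adjusted p up to 0.219).

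Near Evx1 on chromosome 6, 5 genes of the Hoxa cluster and its flanks were tested, of which 2 rose, Hibadh and Tax1bp1, and 1 fell (2 up and 1 down adjusted over the list alone). The Hoxa cluster median was 0.27 (camera adjusted p = 0.430, adjusted p = 0.486 with an estimated correlation). Hoxb1 (−1.70 ± 0.32) and Hoxb9 (−1.34 ± 0.22), the other Hox genes tested, fell (0 up and 2 down adjusted over the list alone). Of 3 germ cell genes Mael fell (−1.01 ± 0.23, 0 up and 1 down adjusted over the list alone). Sp110, the tested marker of the 2-cell-like state (−0.14 ± 0.18), and the Y-linked genes Eif2s3y (0.76 ± 0.46) and Ddx3y (0.10 ± 0.56) did not pass over all genes or adjusted over the list alone. Hibadh and Mael were not called without WT replicate 2 or Evx1as KO replicate 3 (adjusted p up to 0.125). Tax1bp1 was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 2 (adjusted p up to 0.129).

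In all, 3230 of 13188 genes differed between Evx1as KO and WT (limma with Benjamini-Hochberg adjustment), 1721 higher and 1509 lower, and 307 and 355 of them changed at least 2-fold. On chromosome 1, 92 of 728 tested genes were higher and 145 lower, on chromosome 8, 116 and 34 of 752, and on chromosome 14, 27 and 71 of 501. Among the largest rises were those of the embryonic stem cell Ras gene Eras (log2 fold change 2.50 ± 0.29, adjusted p = 0.00135), the peroxisomal oxidase gene Pipox (log2 fold change 2.47 ± 0.14, adjusted p = 2.39e-04) and 2610528J11Rik (log2 fold change 2.70 ± 0.27, adjusted p = 8.94e-04). Car4, Sfrp1, Myb, Ndrg2, Rab25 and Slc27a2 rose by 2.46, 2.45, 2.31, 2.30, 2.22 and 2.17 (log2), with Sfrp1 on chromosome 8 and Ndrg2 on chromosome 14. Lhx1, a LIM homeobox gene, Sprr2a1, Arl4d and Zfp703 had log2 fold changes of −3.50, −3.72, −3.01 and −2.99. AK145379, which spans nearly the same stretch of chromosome 7 as H19 of the imprinted list and is uncertain for that reason, had −3.00. It stood at 7.88 and 24.15 FPKM in WT and at 1.61 or less in every knockout library. H19 itself was listed at 0.314 FPKM or less and was not tested. Where 5 or fewer members of a list moved most of them are named, and those outside the naming rule were chosen after their values were seen. With a preset correlation 16 lists were called, and none of them with an estimated correlation (lowest adjusted p = 0.147 with an estimated correlation). The number of changed genes was 1414 and 1498 without WT replicates 1 and 2, 2117 without Evx1as KO replicate 1 and 1807 without Evx1as KO replicate 3. Car4 was not called without WT replicate 1 or 2 (adjusted p up to 0.116).

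**Figure D3:**
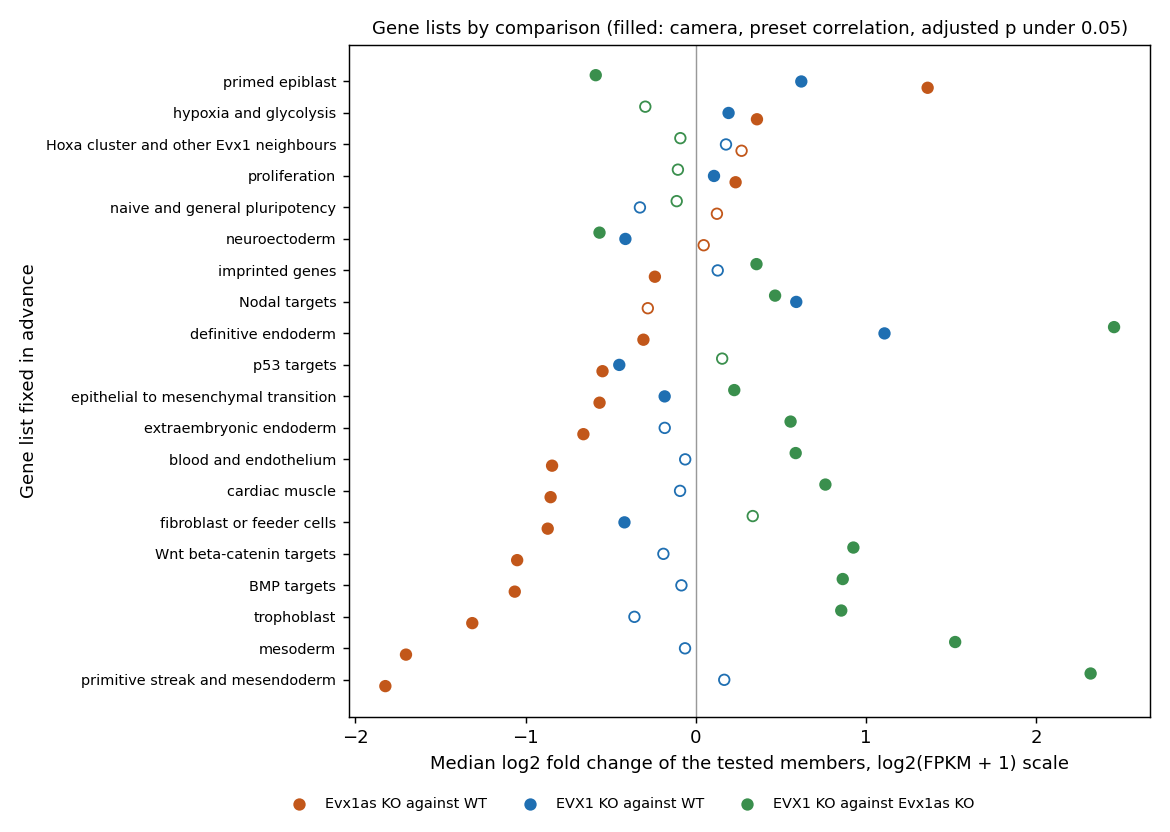
Median log2 fold change of the tested members of each of 20 gene lists (horizontal axis, log2(FPKM + 1) scale) by list (vertical axis), coloured by comparison, with filled points for a camera adjusted p under 0.05 at the preset correlation. The primitive streak and mesendoderm median lies at −1.82 in Evx1as KO against WT, 0.17 in EVX1 KO against WT and 2.32 in EVX1 KO against Evx1as KO.

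The second comparison asked which genes differ between the libraries labelled EVX1 KO and WT. A few primed epiblast genes, Fgf5 and Otx2 among them, were higher, while most streak genes were not called. Fgf5, a growth factor gene of the epiblast, rose from 13.5 ± 0.0406 to 34.9 ± 1.06 FPKM (SD, n = 2 and 3; log2 fold change 1.31 ± 0.08, adjusted p = 7.56e-04). Otx2, a homeobox gene on chromosome 14, rose from 10.9 ± 1.92 to 35.8 ± 3.09 FPKM (log2 fold change 1.64 ± 0.16, adjusted p = 0.0124). Of 11 primed epiblast genes 4 rose, among them Fgf5, Otx2 and Zic2, and 0 fell (6 up and 1 down adjusted over the list alone). The primed epiblast median was 0.62 (camera adjusted p = 0.00125, adjusted p = 0.391 with an estimated correlation). Without the genes of chromosomes 1, 8 and 14, among them Otx2 and Zic2, the list was not called (median 0.34, adjusted p = 0.0767). Otx2 was not called without EVX1 KO replicate 2 (adjusted p = 0.0511), nor was Zic2 without WT replicate 1 or EVX1 KO replicate 2 (adjusted p up to 0.1501). Of 17 naive and general pluripotency genes limma called 0 (8 at an unadjusted p under 0.05, 3 up and 5 down adjusted over the list alone), with Nanog at 1.43 ± 0.29 and Klf2, on chromosome 8, at −2.03 ± 0.43. The pluripotency median was −0.33 (camera adjusted p = 0.109, adjusted p = 0.440 with an estimated correlation), and the list was called without the filter on low FPKM (adjusted p = 0.0469) or in a fit of only the 2 groups (0.0459).

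Cer1, which encodes a secreted Nodal antagonist of endoderm, rose from 0.498 and 0.489 FPKM in WT to 9.84, 12.6 and 5.72 (log2 fold change 2.74 ± 0.40, adjusted p = 0.0266). It was the only gene called over all genes among 11 of definitive endoderm (4 up and 0 down adjusted over the list alone), 10 Nodal targets (4 up and 1 down adjusted over the list alone) and 18 streak genes (2 up and 0 down adjusted over the list alone). The definitive endoderm median was 1.11 (camera adjusted p = 1.37e-04, adjusted p = 0.440 with an estimated correlation) and the Nodal target median 0.59 (camera adjusted p = 0.0407, adjusted p = 0.514 with an estimated correlation). The streak and mesendoderm median was 0.17 (camera adjusted p = 0.146, adjusted p = 0.654 with an estimated correlation). T stood at 170 ± 29.7 FPKM (log2 fold change −0.29 ± 0.42, adjusted p = 0.728), and Mixl1 (0.12 ± 0.60) and Lhx1 (0.98 ± 0.50) did not pass either. The Nodal call was lost without WT replicate 1 (adjusted p = 0.226) or EVX1 KO replicate 1 (0.0979), with a pseudocount of 0.1 (adjusted p = 0.0513) and without the genes of chromosomes 1, 8 and 14 (median 0.33, adjusted p = 0.169). The streak list was called without Evx1as KO replicate 2 (adjusted p = 0.0309) and in a fit of only the 2 groups (adjusted p = 0.0210). Cer1 was not called without WT replicate 1 or 2 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.177). Chromosome 1, which carries Mixl1 and Sox17, lay at 0.14, 0.12 and 0.11 in these libraries.

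Msgn1 was the only mesoderm gene of 12 to fall, from 18.7 and 16.1 FPKM in WT to 2.32, 3.07 and 0.969 (log2 fold change −2.62 ± 0.29, adjusted p = 0.0124; 0 up and 2 down adjusted over the list alone). The mesoderm median was −0.06 (camera adjusted p = 0.254, adjusted p = 0.6298 with an estimated correlation). Mdm2 fell from 91.5 ± 3.62 to 56.0 ± 2.89 FPKM (log2 fold change −0.70 ± 0.09, adjusted p = 0.0214), and Cdkn1a, a cell cycle inhibitor gene induced by p53, from 131 ± 0.207 to 95.2 ± 6.24 (log2 fold change −0.45 ± 0.08, adjusted p = 0.0438). These were the p53 targets that fell, of 15, and 0 rose (0 up and 10 down adjusted over the list alone). The p53 target median was −0.45 (camera adjusted p = 1.35e-06, adjusted p = 0.219 with an estimated correlation). Cdkn2a, the gene of the cell cycle inhibitors p16INK4a and p19ARF, fell from 18.0 ± 0.870 to 3.60 ± 1.12 FPKM (log2 fold change −2.07 ± 0.23, adjusted p = 0.0124). The metallothionein genes Mt1 and Mt2 lie on chromosome 8, which was lower in replicates 1 and 2 labelled EVX1 KO. They fell to 15.2 ± 4.22 and 18.3 ± 6.29 FPKM (log2 fold change −2.12 ± 0.36, adjusted p = 0.0346 and log2 fold change −2.33 ± 0.40, adjusted p = 0.0366), from 108 and 42.1 and from 159 and 54.3 in the WT libraries. Msgn1 was not called without WT replicate 1 or 2 (adjusted p up to 0.1501), nor were Cdkn2a and Mdm2 without WT replicate 1 or 2 or EVX1 KO replicate 2 (adjusted p up to 0.163). Mt1 and Mt2 were not called without WT replicate 1, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.177). Cdkn1a was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.217).

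Of 17 hypoxia and glycolysis genes the growth factor gene Vegfa rose (log2 fold change 1.13 ± 0.18, adjusted p = 0.0293; 3 up and 0 down adjusted over the list alone), and the glycolysis median was 0.19 (camera adjusted p = 0.0407, adjusted p = 0.556 with an estimated correlation). Limma called 0 of 15 proliferation genes (7 at an unadjusted p under 0.05, 4 up and 0 down adjusted over the list alone), and the proliferation median was 0.11 (camera adjusted p = 0.0139, adjusted p = 0.440 with an estimated correlation). It called 0 of 8 neuroectoderm genes (1 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone), and the neuroectoderm median was −0.41 (camera adjusted p = 0.0407, adjusted p = 0.391 with an estimated correlation). Likewise 0 of 12 genes of epithelial to mesenchymal transition were called (4 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.0407, adjusted p = 0.440 with an estimated correlation). The fibroblast and feeder markers had 0 calls of 10 (4 at an unadjusted p under 0.05, 1 up and 3 down adjusted over the list alone) and a median of −0.42 (camera adjusted p = 0.0407, adjusted p = 0.440 with an estimated correlation). Each of these list calls depended on single libraries, and all but proliferation also on the processing. Glycolysis was not called without WT replicate 1 (adjusted p = 0.0733), WT replicate 2 (0.120), Evx1as KO replicate 3 (0.0595), EVX1 KO replicate 1 (0.135) or EVX1 KO replicate 2 (0.0728), nor with a pseudocount of 0.1 (adjusted p = 0.0513) or without the limma trend (0.0635). Proliferation was not called without WT replicate 1 (adjusted p = 0.186), nor was neuroectoderm without WT replicate 1 (adjusted p = 0.0556), WT replicate 2 (0.147), Evx1as KO replicate 1 (0.0700) or EVX1 KO replicate 1 (0.0979). The neuroectoderm call was also lost with a pseudocount of 0.1 (adjusted p = 0.0513), with median-ratio scaling (0.0544), with array weights (0.0939) or in a fit of only the 2 groups (0.0585). Epithelial to mesenchymal transition was not called without WT replicate 1 (adjusted p = 0.226), EVX1 KO replicate 1 (0.0979) or EVX1 KO replicate 2 (0.0693), nor were fibroblasts without WT replicate 1 (adjusted p = 0.0556), WT replicate 2 (0.209), EVX1 KO replicate 1 (0.0979) or EVX1 KO replicate 3 (0.0579). Without the genes of chromosomes 1, 8 and 14 the calls of epithelial to mesenchymal transition (median −0.23, adjusted p = 0.0584) and fibroblasts (median −0.45, adjusted p = 0.0831) were lost, with medians no nearer to 0 than before. The former was also lost with a pseudocount of 0.1 (adjusted p = 0.0513), with a filter of 5 FPKM (0.0965) or with quantile normalization (0.0856), and the latter with a pseudocount of 0.1 (adjusted p = 0.0513), with a filter of 5 FPKM (0.275), with median-ratio scaling (0.0514) or with array weights (0.123). Vegfa was not called without WT replicate 1 or 2, Evx1as KO replicate 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.196).

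The remaining lists had neither a member called by limma nor a list call in the libraries labelled EVX1 KO. Medians were −0.18 (camera adjusted p = 0.427, 5 at an unadjusted p under 0.05, 1 up and 2 down adjusted over the list alone) for extraembryonic endoderm, −0.09 (camera adjusted p = 0.8997, 1 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone) for cardiac muscle and −0.06 (camera adjusted p = 0.487, 1 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone) for blood and endothelium. Wnt targets had a median of −0.19 (camera adjusted p = 0.266, 2 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone) and BMP targets of −0.09 (camera adjusted p = 0.180, 3 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone). For trophoblast it was −0.36 (camera adjusted p = 0.111, 2 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone), for imprinted genes 0.13 (camera adjusted p = 0.265, 8 at an unadjusted p under 0.05, 3 up and 0 down adjusted over the list alone) and for the Hoxa cluster and its flanks 0.18 (camera adjusted p = 0.480, 1 at an unadjusted p under 0.05, 1 up and 0 down adjusted over the list alone). Means of extraembryonic endoderm (0.06) and cardiac muscle (0.14) had the opposite sign to their medians and tests. The trophoblast list was called without Evx1as KO replicate 1 (adjusted p = 0.0433) or 2 (0.0474), and in a fit of only the 2 groups (adjusted p = 0.0417). Hoxb1 (−1.57 ± 0.32) and Hoxb9 (−0.99 ± 0.22) did not pass over all genes (0 up and 2 down adjusted over the list alone). Nor did the germ cell genes Mael (−0.45 ± 0.23), Rhox6 (−0.67 ± 0.33) and Ddx4 (−0.11 ± 0.21), Sp110 (0.39 ± 0.18), Eif2s3y (−0.23 ± 0.46) or Ddx3y (−0.67 ± 0.56), over all genes or adjusted over the list alone.

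In all, 164 of 13188 genes differed between the libraries labelled EVX1 KO and WT (limma with Benjamini-Hochberg adjustment), 91 higher and 73 lower, and 25 and 24 of them changed at least 2-fold. Chromosome 1 held 20 of the higher genes and 1 of the lower, chromosome 8 held 0 and 7, and chromosome 14 held 7 and 2. Jakmip1, the metalloproteinase gene Adamts9, the semaphorin gene Sema6d and 2010107E04Rik rose by 1.38, 1.27, 1.27 and 1.48 (log2). Rises of Rpl39 (1.78), which has pseudogene copies, of AK208404 (1.59), which overlaps Ngfrap1, and of the mitochondrial transcript AK018753 (1.66) are uncertain because reads may be shared. Prph, Vgf and Tdh, which is on chromosome 14, had log2 fold changes of −1.71, −1.62 and −1.67, and AK145379 had −3.05. AK145379, at the position of H19, was not a member of the imprinted list, and H19 was not tested. The number of changed genes was 6 and 28 without WT replicates 1 and 2, 81 and 43 without Evx1as KO replicates 1 and 3, and 42, 4 and 643 without replicates 1, 2 and 3 labelled EVX1 KO. AK145379 was not called without EVX1 KO replicate 2 (adjusted p = 0.0916), nor was Vgf without WT replicate 1 or EVX1 KO replicate 2 (adjusted p up to 0.1501). AK208404 was not called without WT replicate 2 or EVX1 KO replicate 2 (adjusted p up to 0.0932), nor was Tdh without WT replicate 1 or 2 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.165). Jakmip1 and Sema6d were not called without WT replicate 1 or 2, Evx1as KO replicate 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.165). 2010107E04Rik and AK018753 were not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 2 (adjusted p up to 0.217). Adamts9, Rpl39 and Prph were not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.221). With a preset correlation 9 lists were called, and none of them with an estimated correlation (lowest adjusted p = 0.219 with an estimated correlation).

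The third comparison set the knockouts against each other. Most tested streak, mesoderm and definitive endoderm genes were higher in the libraries labelled EVX1 KO than in Evx1as KO. Lhx1, which acts in the streak and head organizer, stood at 43.9 ± 3.25 FPKM in the former and at 0.175, 3.97 and 0.362 in the latter (SD, n = 3; log2 fold change 4.49 ± 0.45, adjusted p = 5.10e-04). Mixl1 stood at 60.7 ± 9.59 against 4.37 ± 5.16 FPKM (log2 fold change 3.95 ± 0.54, adjusted p = 0.00183). Of 18 streak and mesendoderm genes 17 were higher and 0 lower (18 up and 0 down adjusted over the list alone), and the streak and mesendoderm median was 2.32 (camera adjusted p = 1.13e-13, adjusted p = 0.180 with an estimated correlation). Gata4 stood at 19.8 ± 6.73 against 0.524 ± 0.258 FPKM (log2 fold change 3.74 ± 0.31, adjusted p = 3.18e-04), and the chemokine receptor gene Cxcr4 differed by 3.87 ± 0.32. Of 11 definitive endoderm genes 7 were higher and 0 lower (8 up and 0 down adjusted over the list alone), and the definitive endoderm median was 2.46 (camera adjusted p = 3.30e-06, adjusted p = 0.180 with an estimated correlation). Kdr differed by 2.57 ± 0.34, and of 12 mesoderm genes 9 were higher and 0 lower (9 up and 0 down adjusted over the list alone). The mesoderm median was 1.52 (camera adjusted p = 3.30e-06, adjusted p = 0.180 with an estimated correlation). Mixl1 and Cxcr4 lie on chromosome 1, higher in the libraries labelled EVX1 KO, and Gata4 on chromosome 14, lower in Evx1as KO replicates 2 and 3.

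Msx1 was higher by 4.36 ± 0.47 and Cdx2 by 2.47 ± 0.20 (log2) in the libraries labelled EVX1 KO. Of 14 Wnt targets 8 were higher and 0 lower (10 up and 0 down adjusted over the list alone), and the Wnt target median was 0.92 (camera adjusted p = 3.30e-06, adjusted p = 0.180 with an estimated correlation). Of 11 BMP targets 9 were higher and 0 lower (10 up and 0 down adjusted over the list alone), and the BMP target median was 0.86 (camera adjusted p = 3.92e-06, adjusted p = 0.180 with an estimated correlation). Trophoblast markers were higher in 8 of 10 cases and lower in 0 (8 up and 0 down adjusted over the list alone), with a median of 0.85 (camera adjusted p = 5.55e-06, adjusted p = 0.190 with an estimated correlation). Of 10 Nodal targets Cer1, Gsc, Eomes and, on chromosome 1, Lefty2 were higher and Gdf3 lower (6 up and 1 down adjusted over the list alone), and the Nodal target median was 0.46 (camera adjusted p = 0.00276, adjusted p = 0.224 with an estimated correlation). Of 12 genes of epithelial to mesenchymal transition Cdh2, Cdh11 (chromosome 8), Snai1 and Fn1 (chromosome 1) were higher and 0 lower (6 up and 1 down adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0186, adjusted p = 0.224 with an estimated correlation). That call was lost without EVX1 KO replicate 3 (adjusted p = 0.0568) and without the genes of chromosomes 1, 8 and 14 (median 0.20, adjusted p = 0.0628). Gdf3 was not called without any Evx1as KO replicate or any EVX1 KO replicate (adjusted p up to 0.117).

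Of 10 extraembryonic endoderm genes Gata4, Gata6, Sox17 (chromosome 1), Sparc and Lamb1 were higher and Apoe lower in the libraries labelled EVX1 KO (6 up and 1 down adjusted over the list alone). The extraembryonic median was 0.56 (camera adjusted p = 9.24e-04, adjusted p = 0.180 with an estimated correlation). Of 5 cardiac muscle genes Myl7, Tnnc1 and Actc1 were higher (3 up and 0 down adjusted over the list alone), and the cardiac median was 0.76 (camera adjusted p = 0.0385, adjusted p = 0.224 with an estimated correlation). That list was not called without Evx1as KO replicate 1 (adjusted p = 0.0724), Evx1as KO replicate 2 (0.0856) or EVX1 KO replicate 2 (0.0532). Of 4 blood and endothelium genes Kdr, Gata2 and Runx1 were higher (4 up and 0 down adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.00695, adjusted p = 0.190 with an estimated correlation), and the call was lost without the filter on low FPKM (adjusted p = 0.0504). Peg10 stood at 385 ± 11.6 against 150 ± 24.6 FPKM (log2 fold change 1.36 ± 0.12, adjusted p = 3.24e-04). Of 21 imprinted genes 8 were higher and Grb10 lower (8 up and 1 down adjusted over the list alone), and the imprinted median was 0.36 (camera adjusted p = 0.00433, adjusted p = 0.180 with an estimated correlation). Myl7 was not called without Evx1as KO replicate 3 or EVX1 KO replicate 2 (adjusted p up to 0.0560), nor was Grb10 without Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 (adjusted p up to 0.0748). Apoe, Actc1 and Runx1 were not called without any Evx1as KO replicate or EVX1 KO replicate 2 or 3 (adjusted p up to 0.160). Tnnc1 was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 2 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.152). Lamb1 was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.116). Gata2 was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or any EVX1 KO replicate (adjusted p up to 0.131).

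Some primed epiblast and neural genes, Foxd3 and Sox3 among them, were lower in the libraries labelled EVX1 KO than in Evx1as KO. Foxd3 stood at 0.232 ± 0.112 against 6.14 ± 0.499 FPKM (log2 fold change −2.54 ± 0.13, adjusted p = 7.22e-05) and Sox3 at 3.05 ± 0.842 against 25.1 ± 5.86 (log2 fold change −2.68 ± 0.22, adjusted p = 3.18e-04). Otx2 (−0.12 ± 0.15) and Fgf5 (0.13 ± 0.07) did not pass. Of 11 primed epiblast genes Foxd3, Dnmt3b, Zic2, Sall2 and Dnmt3a were lower and Lef1 higher (2 up and 5 down adjusted over the list alone), and the primed epiblast median was −0.59 (camera adjusted p = 0.0338, adjusted p = 0.230 with an estimated correlation). Of 8 neuroectoderm genes 3 were lower, Sox3, Sox1 and Neurod1, and 1 was higher (1 up and 3 down adjusted over the list alone), and the neuroectoderm median was −0.57 (camera adjusted p = 0.0338, adjusted p = 0.180 with an estimated correlation). Without the genes of chromosomes 1, 8 and 14, among them Zic2 and Sall2 of the primed epiblast list, both calls were lost. The median was then −0.39 for primed epiblast (adjusted p = 0.220) and −0.63, no nearer to 0, for neuroectoderm (adjusted p = 0.258). The primed epiblast call was also lost without EVX1 KO replicate 3 (median −0.22, adjusted p = 0.0873) and with array weights (median −0.66, adjusted p = 0.0559). The neuroectoderm call was lost without WT replicate 2 (adjusted p = 0.0717), Evx1as KO replicate 1 (0.0703), Evx1as KO replicate 2 (0.0548) or EVX1 KO replicate 1 (0.0736), and without the filter on low FPKM (adjusted p = 0.0676), with array weights (0.0675) or in a fit of only the 2 groups (0.0756). Of 17 pluripotency genes Sox2, Utf1, Dppa5a, Fgf4 and Pou5f1 were lower and Tbx3 and Klf5 (chromosome 14) higher (5 up and 5 down adjusted over the list alone), and the pluripotency median was −0.11 (camera adjusted p = 0.377, adjusted p = 0.514 with an estimated correlation). Klf5 was not called without EVX1 KO replicate 2 (adjusted p = 0.0527), nor was Sall2 without Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 (adjusted p up to 0.0705). Neurod1 was not called without Evx1as KO replicate 2 or 3 or any EVX1 KO replicate (adjusted p up to 0.119). Pou5f1 was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 2 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.129).

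Of 15 p53 targets Phlda3, Cdkn1a and Btg2 were higher and Bax, Bbc3 and Zmat3 lower in the libraries labelled EVX1 KO (4 up and 3 down adjusted over the list alone). The p53 target median was 0.15 (camera adjusted p = 0.298, adjusted p = 0.514 with an estimated correlation), and Phlda3 and Btg2 lie on chromosome 1. Pfkl and Pgk1 of 17 hypoxia and glycolysis genes were lower (0 up and 2 down adjusted over the list alone), and the glycolysis median was −0.30 (camera adjusted p = 0.0827, adjusted p = 0.496 with an estimated correlation). That list was called without Evx1as KO replicate 2 (adjusted p = 0.0361) or EVX1 KO replicate 1 (0.0192), and without the filter on low FPKM (adjusted p = 0.0350). Mcm5 and Mcm2 of 15 proliferation genes were lower (0 up and 2 down adjusted over the list alone), and the proliferation median was −0.11 (camera adjusted p = 0.193, adjusted p = 0.514 with an estimated correlation). Mcm5 lies on chromosome 8. Col5a1, Fbln2 and Col1a1 of 10 fibroblast and feeder markers were higher and Mmp2, on chromosome 8, was lower (4 up and 2 down adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.193, adjusted p = 0.429 with an estimated correlation). Of 5 genes of the Hoxa cluster and its flanks 1 was higher and 1, Hibadh, was lower (1 up and 1 down adjusted over the list alone), with a median of −0.09 (camera adjusted p = 0.887, adjusted p = 0.890 with an estimated correlation). Bax was not called without EVX1 KO replicate 2 (adjusted p = 0.0585), nor was Fbln2 without Evx1as KO replicate 3 or EVX1 KO replicate 2 (adjusted p up to 0.0774). Pgk1 and Mcm5 were not called without Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 (adjusted p up to 0.0841). Cdkn1a and Btg2 were not called without Evx1as KO replicate 1 or 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.0838). Bbc3 and Pfkl were not called without Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 or 3 (adjusted p up to 0.0999). Col1a1 was not called without Evx1as KO replicate 2 or 3 or any EVX1 KO replicate (adjusted p up to 0.134). Hibadh was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or EVX1 KO replicate 2 or 3 (adjusted p up to 0.149). Zmat3 was not called without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.145).

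Sp110, the tested marker of the 2-cell-like state, was higher (0.53 ± 0.16; 1 up and 0 down adjusted over the list alone). Hoxb1 (0.14 ± 0.29), Hoxb9 (0.35 ± 0.20), Mael (0.56 ± 0.21), Rhox6 (−0.12 ± 0.30), Ddx4 (0.10 ± 0.19), Eif2s3y (−0.99 ± 0.41) and Ddx3y (−0.77 ± 0.50) did not pass over all genes or adjusted over the list alone. Mt1 and Mt2, on chromosome 8, had log2 fold changes of −3.58 and −3.81, and Pipox and Slc27a2 of −2.66 and −2.70. In all, 2903 of 13188 genes differed between the knockouts (limma with Benjamini-Hochberg adjustment), 1412 higher and 1491 lower in the libraries labelled EVX1 KO, and 279 and 254 of them changed at least 2-fold. On chromosome 8, 14 were higher and 205 lower, on chromosome 14, 145 and 18, and on chromosome 1, 233 and 47. The number of changed genes was 1824 and 1401 without Evx1as KO replicates 1 and 3, and 1451 without EVX1 KO replicate 2. Sp110 was not called without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or any EVX1 KO replicate (adjusted p up to 0.133). With a preset correlation 14 lists were called, and none of them with an estimated correlation (lowest adjusted p = 0.180 with an estimated correlation).

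Changes against WT were then set side by side, since both knockouts were compared with the same WT libraries. Genes that rose in both numbered 49, among them Fgf5, Otx2, Zic2 and Vegfa, against 11.9 for independent lists of these sizes. Genes that fell in both numbered 50, among them Msgn1, Mdm2, Cdkn1a and Cdkn2a, against 8.35. With 1 library left out these numbers were 4 and 1 without WT replicate 1 and 12 and 9 without WT replicate 2. They were 19 and 24, 36 and 32, and 13 and 16 without Evx1as KO replicates 1, 2 and 3, and 17 and 13, 2 and 2, and 151 and 164 without replicates 1, 2 and 3 labelled EVX1 KO. Cdkn2a stood at 2.44 ± 0.757 FPKM in Evx1as KO (log2 fold change −2.49 ± 0.23, adjusted p = 6.41e-04). Mt1 and Mt2 rose in Evx1as KO (log2 fold change 1.46 ± 0.36, adjusted p = 0.0188 and log2 fold change 1.48 ± 0.40, adjusted p = 0.0268) and fell in the libraries labelled EVX1 KO. Lbr, a nuclear envelope gene on chromosome 1, fell in Evx1as KO (−0.46 ± 0.07) and rose in the libraries labelled EVX1 KO (0.41 ± 0.07). Vegfa was not called in Evx1as KO without WT replicate 1 (adjusted p = 0.0572), nor was Mt1 without WT replicate 2 or Evx1as KO replicate 3 (adjusted p up to 0.114). Mt2 was not called in Evx1as KO without WT replicate 2 or Evx1as KO replicate 1 or 3 (adjusted p up to 0.160). Lbr was not called in the libraries labelled EVX1 KO without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.217). The rises of Mt1 and Mt2 in Evx1as KO were 0.79 and 0.71 (log2) without WT replicate 2, and 2.13 and 2.25 without WT replicate 1.

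In 100 simulations of unchanged groups against shared WT libraries, at most 1 gene was called in the same direction in both, but such groups give few calls at all. Simulations added after seeing the data therefore kept the fold changes of called genes, with those of EVX1 KO moved to random genes. They called on average 102 genes in EVX1 KO and had 8.42 rises (at most 17) and 6.34 falls (at most 14) in both. Log2 fold changes of the knockouts correlated across genes at r = 0.445 (rho = 0.468), against 0.599 in simulations without effects. Their covariance was 0.0760 against 0.0218, a difference of 0.0541. With a different WT library for each knockout r was 0.265 and 0.244. Part of the excess overlap may come from the shared WT libraries, since a split leaves 1 WT library per knockout. Of the 1721 genes that rose in Evx1as KO, 955 were lower in EVX1 KO in the direct test and 5 higher. Of the 1509 that fell, 785 were higher and 6 lower. The choice used the same Evx1as KO libraries, which favours these directions whether or not EVX1 KO changed. Over all 1721 and 1509, medians in EVX1 KO against WT were 0.22 and −0.23 (log2). These genes were chosen against the same WT libraries, and simulated medians with effects on unrelated genes averaged 0.023 and −0.022. With genes chosen against 1 WT library and EVX1 KO set against the other, the medians were 0.19 and 0.15 for genes that rose and −0.16 and −0.17 for genes that fell.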

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

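The tests of wrong labels and of antisense reads for Evx1, the test of a state of the WT cultures, and the fit without chromosomes 1, 8 and 14 were chosen only after the result was seen. Lbr, Mt1 and Mt2 were called in opposite directions against WT in the 2 knockouts, with a direct test of the difference. Lbr, on chromosome 1, differed by 0.87 ± 0.07 (log2) between EVX1 KO and Evx1as KO (limma adjusted p = 2.39e-04). Mt1 and Mt2, on chromosome 8, differed by −3.58 ± 0.32 (adjusted p = 3.58e-04) and −3.81 ± 0.36 (adjusted p = 4.28e-04).

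In EVX1 KO replicates 1 and 2, genes of chromosome 8 had medians of −0.51 and −0.44 (ratios of 0.702 and 0.738, 504 genes). In Evx1as KO replicates 2 and 3, genes of chromosome 14 had medians of −0.50 and −0.48 (0.709 and 0.719, 322 genes). Both chromosomes were thus lower there than in the libraries not named for them, which served as reference. A few strongly changed genes are argued against, since at least 87.3% of the genes of the chromosome lay below the median of the other chromosomes in each case. GC content, transcript length and expression level are argued against as the whole cause, since the medians stayed at −0.43 or lower after a fit on all of them. A difference in chromosome copy number may be the source, but it was not settled. Ratios between libraries cannot tell a loss in the lower libraries from a gain in the reference libraries. Medians of 5 position bins ran from −0.56 to −0.49 and from −0.49 to −0.18 on chromosome 8 in EVX1 KO replicates 1 and 2. On chromosome 14 they ran from −0.55 to −0.18 and from −0.60 to −0.24 in Evx1as KO replicates 2 and 3. Thus 2 of the 4 met the bound of −0.2 set beforehand in every bin and 2 missed it. An effect of the edits on these chromosomes stays open and untested, and the shift differed between replicates of the same knockout.

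Evx1 transcript stood as high in the libraries labelled EVX1 KO as in WT. For replicates 1 and 2, libraries of the same cultures as WT under a wrong label are argued against, since the deviation of chromosome 8 from the nearer WT library was −0.32 (log2) or lower. For replicate 3 the same is argued against, since on a scale from the WT mean (0) to the EVX1 KO mean (1) it lay at least 0.389 beyond a WT library left out with it, over 200 genes chosen without both. Like replicates 1 and 2, it lay above WT on chromosomes 14 (0.15, WT up to 0.05) and 1 (0.11, WT up to 0.03). On chromosome 8 it lay within WT (0.07, WT 0.01 and 0.11). It correlated at r = 0.980 and 0.983 with WT and 0.979 and 0.986 with replicates 1 and 2. Left out alone, its position (0.622) was too near WT replicate 2's (0.440) to settle this. Reads of the antisense Evx1as counted as Evx1 cannot be told apart from Evx1 reads, since a ratio of Evx1 to Evx1as of at least 2.37 decides nothing while the strand of the counting is not stated, and other wrong labels and an edit that leaves the transcript in place could also give this level and were not tested.

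Of 15 p53 targets 10 fell and 1 rose in Evx1as KO and 2 fell in the libraries labelled EVX1 KO, with list medians of −0.55 and −0.45 whose calls were both lost with an estimated correlation (adjusted p = 0.147 and 0.219). Independent chance values of the shared WT libraries are argued against, since 0 of 10000 simulated sets of unchanged libraries had both medians as low. Genes varied independently in these sets, so a chance shift shared by the list's genes is not argued against. A single WT library is argued against as well, since the highest median with either WT library left out was −0.42. A state of the WT cultures, such as stress or time in culture, cannot be told apart from an effect shared by both edits, because both comparisons against WT rest on the same WT libraries, and the list median between the knockouts, which uses none of them as control, was 0.15. A shared effect of the edits or of the editing procedure stays open and untested.

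Of the splits of the 6 knockout libraries into 3 and 3, 1 of 10 gave as many genes as the real split, which is the real split itself. The real split gave 2903 genes and the highest of the other splits 1, and 10 splits are too few for a share under 0.05.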

How the results depend on the processing

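The fit without chromosomes 1, 8 and 14 was chosen after seeing the data, and the other alternatives beforehand. Counts of changed genes (3230, 164 and 2903 in the order Evx1as KO against WT, EVX1 KO against WT, and EVX1 KO against Evx1as KO) stayed within 1.5 times under a pseudocount of 0.1, a filter of 5 FPKM, both scalings, robust moderation and the fit without chromosomes 1, 8 and 14 (2906, 167 and 2260). The count for EVX1 KO against WT fell to 28 without a filter, 78 without trend and 35 in a fit of only the groups compared, and rose to 1148 with array weights, which also gave 5552 for EVX1 KO against Evx1as KO. Without a filter more genes were tested, and the smaller fit had fewer samples. For the trend and the weights the cause was not tested. A minimum change of 2-fold left 662, 49 and 533 genes by its construction. With 1 library left out the counts ranged from 1414 to 3427, from 4 to 643 and from 1401 to 2671, the extremes being without WT replicate 1 and EVX1 KO replicate 1, without EVX1 KO replicates 2 and 3, and without Evx1as KO replicate 3 and WT replicate 1. Fewer samples can lower the counts, but EVX1 KO against WT gave 42, 4 and 643 genes without EVX1 KO replicates 1, 2 and 3. The counts thus also depended on which library was left out, and the cause was not tested.

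With the replicate block the counts were 2575, 28 and 2564. Deviations of libraries with the same number correlated at 0.014, 0.066 and −0.10 between Evx1as KO and EVX1 KO for numbers 1, 2 and 3, and between −0.01 and 0.08 with WT. Of 6 knockout libraries 2 correlated best with their own number in the other knockout. The libraries thus share only a number, and calls lost under the block do not speak for a weaker effect.

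The 39 list calls of the comparisons together became 29 to 44 under the alternatives, with 29 to 39 when a library was left out. List results kept their direction and side of the threshold in 1091 of 1173 values, lost the call in 71 and gained it in 11; a called list turned its direction in 0, and an uncalled one its sign in 19. A minimum fold change does not enter the list tests. Named genes did so in 3660 of 4252 values over 218 results, lost the call in 576 and gained it in 16, with 0 called genes reversed and 25 uncalled sign changes. Correlation of the knockouts' log2 fold changes (0.445) lay between 0.370 and 0.484 with all libraries and between 0.377 and 0.519 with a library left out. Genes or lists that a stricter filter, the loss of a library or the loss of chromosomes removed from testing gave no value. Unknown depth limits what low genes can show, and changes of 1.5-fold were often missed in simulated data.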

Other observations

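The genes named here were chosen after their values were seen, and calls are by limma's adjusted p. Cdkn2b, which encodes the cell cycle inhibitor p15INK4b and lies beside Cdkn2a on chromosome 4, stood at 3.69 ± 0.238 FPKM in WT, 0.801 ± 0.381 in Evx1as KO and 1.02 ± 0.0414 in EVX1 KO (SD, n = 2, 3 and 3). It fell in both knockouts (log2 fold change −1.40 ± 0.20, adjusted p = 0.00253, and log2 fold change −1.22 ± 0.20, adjusted p = 0.0319). Every knockout library lay below both WT libraries for Cdkn2a (4.88 FPKM or less against 17.4 or more) and for Cdkn2b (1.10 or less against 3.52 or more). Cdkn2b was not called in EVX1 KO without WT replicate 1 or 2, Evx1as KO replicate 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.179).

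Other genes outside the lists also changed in the same direction in both knockouts. Igfbp7, a secreted binding protein gene, fell by 1.35 in Evx1as KO and 1.31 in EVX1 KO (log2). The falls were 0.69 and 1.08 for the matricellular gene Ctgf, 0.96 and 0.76 for the desmosomal gene Perp, and 0.87 and 0.89 for Rprm, a cell cycle arrest gene. Scd1, which encodes a fatty acid desaturase, rose by 1.22 and 1.01. The asparagine synthetase gene Asns rose by 0.48 and 0.73, and Pck2, a mitochondrial carboxykinase gene on chromosome 14, by 1.07 and 1.16. Asns was not called in Evx1as KO without WT replicate 1 (adjusted p = 0.0794), nor was Ctgf without WT replicate 1 or 2 (adjusted p up to 0.0873). Scd1 was not called in EVX1 KO without WT replicate 1 or EVX1 KO replicate 2 (adjusted p up to 0.1501), nor was Asns without WT replicate 1 or 2 or EVX1 KO replicate 2 (adjusted p up to 0.165). Ctgf and Pck2 were not called in EVX1 KO without WT replicate 1 or 2 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.179). Igfbp7 was not called in EVX1 KO without WT replicate 1 or 2, Evx1as KO replicate 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.1501). Rprm was not called in EVX1 KO without WT replicate 1 or 2, Evx1as KO replicate 1 or 3 or EVX1 KO replicate 1 or 2 (adjusted p up to 0.1501). Perp was not called in EVX1 KO without WT replicate 1 or 2, any Evx1as KO replicate or EVX1 KO replicate 1 or 2 (adjusted p up to 0.180). Malat1, an abundant nuclear RNA from chromosome 19, stood at 48.3 ± 9.18 FPKM in WT, 7.15, 13.5 and 9.32 in the Evx1as KO libraries and 32.3 ± 14.4 in EVX1 KO, and was called in Evx1as KO (log2 fold change −2.19 ± 0.35, adjusted p = 0.00359) and not in EVX1 KO (log2 fold change −0.64 ± 0.35, adjusted p = 0.318).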
